A study of Mus musculus with 8 samples.

How the data were processed

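Total RNA of micro-dissected mouse organ of Corti at postnatal day 0 was isolated with RNeasy columns, depleted of ribosomal RNA and made into libraries with the NEBNext Ultra II kit, per the labels' protocols. The 8 libraries, 4 wildtype and 4 labelled conditional Prox1 knockout, were grouped by the genotype in the labels, and table columns were assigned to libraries by the library names in the labels. The submitters' processing notes name FastQC 0.12.1, cutadapt 4.3, HISAT2 2.2.1, featureCounts and DESeq2, the last 2 without a version, and the genome build GRCm39. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

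The authors deposited raw counts per gene for each library, per the file headers and the values, which are whole numbers. Beside them the deposited tables give the mean and the SD of the 4 raw counts of a group, and a mean of normalized counts over all libraries, as a signal; these columns were described but not tested. The authors also deposited a DESeq2 comparison with a log2 fold change and its standard error, a test score (the Wald statistic), a p-value and an adjusted p-value per gene, per the file headers. The direction of that comparison is not stated in the file and was read from its signs, which match knockout over wildtype as labelled. A rerun of DESeq2 1.42.0 on the deposited counts gave log2 fold changes that differed by over 0.01 in 0 genes. It called 35 genes higher and 48 lower, and 83 of the 86 genes called in the deposited table were among them.

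From the counts, 20581 of 41079 genes were kept with edgeR's filterByExpr (minimum count 10), 8065 genes having no count in any library. The kept genes hold between 99.90 and 99.93% of the counts of each library. Libraries were scaled by TMM, and CPM values use these factors. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with genotype as the single factor and Benjamini-Hochberg adjustment over all tested genes, with a threshold of 0.05. Fold changes are those of the libraries labelled knockout over wildtype, as log2 with the SE of the fit. Scalar comparisons of libraries used two-sided exact permutation tests over 70 assignments.

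The 32 gene lists (cell types of the organ of Corti, signalling pathways, innervation, and tissues that a dissection could carry along) were fixed before the data were examined, as were the tests, all alternative settings but 4 and the rule for named genes. Prox1 was left out of the lists. Lists were tested with camera of limma 3.58.1 on log2 CPM with a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the lists, and lists with under 5 tested genes were to be left out, which applied to 0 lists. Alternatives were an estimated correlation and fry. The genes named are Prox1 and Emx2, up to 10 genes per direction with the most extreme fold change among those past the threshold with an average log2 CPM of at least 2, non-overlapping groups and a symbol that is not a clone or number name, and, from each list, up to 3 genes past the threshold over all genes or else the gene with the smallest p. List members beyond these, and genes said to be so, were chosen after their values were seen. A few genes under this rule are not reported here. Gene classes and neighbours were taken by symbol from the RefSeq table of GRCm38.p6, an older assembly than that of the authors, which matched 94.7% of the tested genes, and positions on that assembly served only to tell which genes neighbour or overlap one another.

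Alternatives were other scalings (RLE, upper quartile), no filter and a stricter filter of 50 counts in at least 4 libraries, DESeq2, limma-voom with and without sample quality weights, the replicate number as a block, a sex score as a covariate, removal of 37 mitochondrial, 8 haemoglobin and 55 ribosomal RNA genes, each library left out in turn, and adjusted p thresholds of 0.01 and 0.1. Alternatives chosen after the data were seen were leaving out the wildtype libraries 1 and 3, the stria score or the share of lncRNA counts as a covariate, and protein-coding genes alone. No pair of libraries of a group agreed within sampling noise: the lowest chi-square per degree of freedom over genes was 10.7.

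The tests were tried on simulated data with the means and library sizes of these libraries, in which 200 genes were changed. For Prox1 knockout against wildtype over 20342 simulated genes, edgeR recovered 16% of 50 genes changed by 1.25-fold, 64% at 1.5-fold, 96% at 2-fold and 100% at 4-fold, and 15 unchanged genes were called, 9.8% of its calls. With DESeq2, whose step ran on 20581 simulated genes of this comparison, 26 unchanged genes were called, 15.6% of its calls. In simulated lists shifted by -0.3 on the log2 scale, over 20357 genes, camera with the preset correlation called 5 of 5 shifted lists and 0 of 25 others. Genes were drawn independently of one another there, so these counts do not show how the preset correlation performs where genes of a list vary together. Changes of 1.25-fold were thus mostly missed at this depth and number of libraries. Figures were drawn with matplotlib 3.10.9.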

Results

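Gene expression was measured by sequencing of total RNA, after depletion of ribosomal RNA, in 8 libraries of micro-dissected organ of Corti, the sensory epithelium of the mouse cochlea, taken on the day of birth (P0). The 4 wildtype libraries were compared with 4 libraries labelled conditional Prox1 knockout, in which Emx2-cre acts on a floxed Prox1 gene, to find genes and cell types whose expression differs when Prox1 is deleted. The wildtype libraries 1 to 4 held 39886702, 42318233, 35450437 and 32863533 counts, and the libraries labelled knockout 1 to 4 held 29908965, 32548009, 32582542 and 32613549. Each library labelled knockout was sequenced less deeply than each wildtype library (exact permutation p = 0.0286, two-sided, n = 4 per group, the smallest p this design allows). Of 41079 genes, 20581 passed the low-count filter. The correlation of log2 CPM between any pair of libraries, taken across genes, lay between 0.984 and 0.993. The labels do not say that the libraries came from separate animals, so p-values measure the spread between these samples, which may be technical.

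Prox1, the homeobox transcription factor targeted in this design, was higher in the libraries labelled knockout, which goes against the label. Its counts-per-million (CPM) values were 109, 114, 106 and 115 in the wildtype libraries 1 to 4 and 147, 137, 138 and 133 in the libraries labelled knockout 1 to 4. The means were 111 ± 4.29 and 139 ± 5.71 CPM (SD, n = 4 per group), a log2 fold change of 0.33 ± 0.05 (SE) with an adjusted p of 0.0298 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The exact permutation test of log2 CPM gave p = 0.0286 (two-sided, 70 assignments, n = 4 per group). The counts cover Prox1 as 1 gene, and reads of a floxed part were not analysed here, so the level of the whole transcript does not show whether the floxed part was lost. Without any 1 of the libraries other than library 4 labelled knockout, the adjusted p was between 0.0599 and 0.180 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, while the log2 fold change stayed between 0.30 and 0.34. Emx2, the locus that drives Cre, had 16.2 ± 1.61 CPM in wildtype and 19.7 ± 2.39 CPM in the libraries labelled knockout (SD, n = 4 per group), a log2 fold change of 0.28 ± 0.10 (SE) that did not pass. Because Prox1 went against its label, all directions below are stated for the libraries as labelled.

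Across the tested genes, 7 were higher and 12 lower in the libraries labelled knockout. The thyrotropin-releasing hormone gene Trh rose most, from 8.89 ± 8.37 to 65.5 ± 9.25 CPM (SD, n = 4 per group), a log2 fold change of 2.90 ± 0.43 (SE). Kcng3, a potassium channel subunit, rose from 2.65 ± 0.50 to 7.18 ± 0.73 CPM, which is 2.71-fold. Smaller increases were found for the ectonucleotidase gene Enpp3 (log2 fold change 0.63 ± 0.09), for Mdm1, which encodes a microtubule-binding protein of centrioles (0.63 ± 0.05), and for the phosphate transporter gene Slc20a1 (0.52 ± 0.08). The remaining 2 genes called higher were Prox1 and Gm13166, whose log2 fold change was 0.64 ± 0.09. Wildtype library 4 held 21.4 CPM of Trh against 4.14 to 5.80 CPM in the other wildtype libraries, and without it the log2 fold change was 3.80. In fits chosen after the data were seen, the log2 fold change of Trh was 2.39 without the wildtype libraries 1 and 3 and 1.97 ± 0.35 with the stria score, the mean log2 CPM of a list of stria vascularis and melanocyte genes, as a covariate. It passed in neither (adjusted p = 0.232 and 0.188 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Trh and Slc20a1 did not pass without wildtype library 1 or 3 or without library 1, 2 or 3 labelled knockout, and Enpp3 did not pass without any 1 of the 8 libraries.

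**Figure D1:**
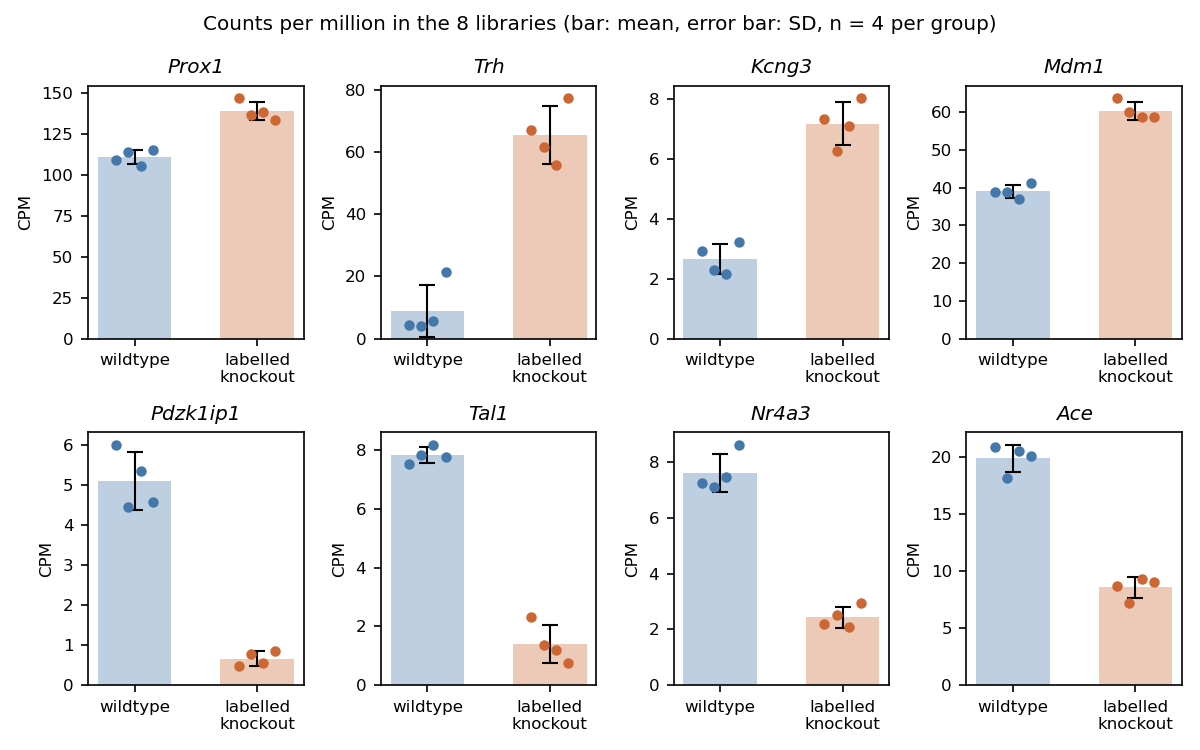
CPM values of 8 genes in each library, with 1 panel per gene and a linear vertical axis from 0, where bars are group means, error bars are SD (n = 4 per group) and points are libraries 1 to 4 from left to right.  Prox1 lay between 106 and 115 CPM in wildtype and between 133 and 147 CPM in the libraries labelled knockout, and wildtype library 4 lay apart for Trh at 21.4 CPM.

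Among the genes that fell, Pdzk1ip1, which encodes a small membrane protein and belongs to the Deiters cell list, showed the lowest log2 fold change, with 5.09 ± 0.72 CPM in wildtype and 0.66 ± 0.18 CPM in the libraries labelled knockout (SD, n = 4 per group), 7.65-fold higher in wildtype. Its log2 fold change was -2.94 ± 0.21 (SE), with an adjusted p of 0.000132 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Tal1, a basic helix-loop-helix transcription factor of blood and endothelial lineages and the tested gene next to Pdzk1ip1 in the RefSeq order of GRCm38, fell from 7.83 ± 0.28 to 1.41 ± 0.65 CPM. The nuclear receptor gene Nr4a3 fell from 7.62 ± 0.69 to 2.43 ± 0.37 CPM, and Ace, the angiotensin-converting enzyme gene, from 19.9 ± 1.18 to 8.55 ± 0.94 CPM. The channel gene Pkd2l1 had a log2 fold change of -1.05 ± 0.16 (SE), the ciliary gene Cep41 one of -0.87 ± 0.08 and Arhgap27 one of -0.50 ± 0.08. Another 4 genes that fell were chosen after their values were seen, as was Gm13166 above: Gm45645 (-2.23 ± 0.29), Marchf4 (-1.65 ± 0.16), Ccbe1 (-1.26 ± 0.19) and Gm13782, from 15.9 ± 1.63 to 7.90 ± 0.81 CPM. Pkd2l1 and Arhgap27 passed in 1 of the 8 fits with a library left out, the one without wildtype library 2. Ccbe1 passed in 2 of these fits, those without wildtype library 4 and without library 4 labelled knockout, and Gm45645 did not pass without library 1 labelled knockout. Gm13166 did not pass without wildtype library 1, 2 or 4 or without library 2 or 3 labelled knockout. Gm13782 overlaps Cep41 in the annotation, and reads of such overlapping genes cannot be told apart where the strand setting of the counting is not given.

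For each of the 19 genes, the libraries of one group all lay above those of the other. This held for 759 of the 20581 tested genes (3.69%), and chance gives 2.86% for 4 libraries against 4. Of the 19 genes, 7 changed by less than 2-fold. At an unadjusted p under 0.05 in edgeR's test, 980 genes were higher and 573 lower, against 1029 expected by chance in total if genes vary independently. Other splits of the 8 libraries into 4 and 4 gave between 247 and 6121 such genes, against 1553 for the real one. Several of them exceeded it, so this excess cannot be tied to genotype. Pdzk1ip1, Ace, Nr4a3, Tal1, Cep41, Marchf4, Gm13782 and Mdm1 passed the threshold under each of the alternatives that tested them. With 1 library left out, between 2 and 7 genes were called higher, with 2 or 3 without wildtype library 1 or 3 or library 1, 2 or 3 labelled knockout, and between 8 and 20 lower, with 20 without library 4 labelled knockout. Xist and Y-linked genes were counted in all 8 libraries. Xist had 563 to 1293 CPM in wildtype and 574 to 807 CPM in the libraries labelled knockout, and the Y-linked Ddx3y 24.7 to 44.1 and 38.7 to 59.2 CPM. These values argue against libraries of 1 animal each. The mean log2 CPM of the Y-linked genes was 4.60 ± 0.36 in wildtype and 5.17 ± 0.15 in the libraries labelled knockout (SD, n = 4 per group; exact permutation p = 0.0571, two-sided). With a sex score as a covariate, 2 genes were called higher and 7 lower.

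**Figure D2:**
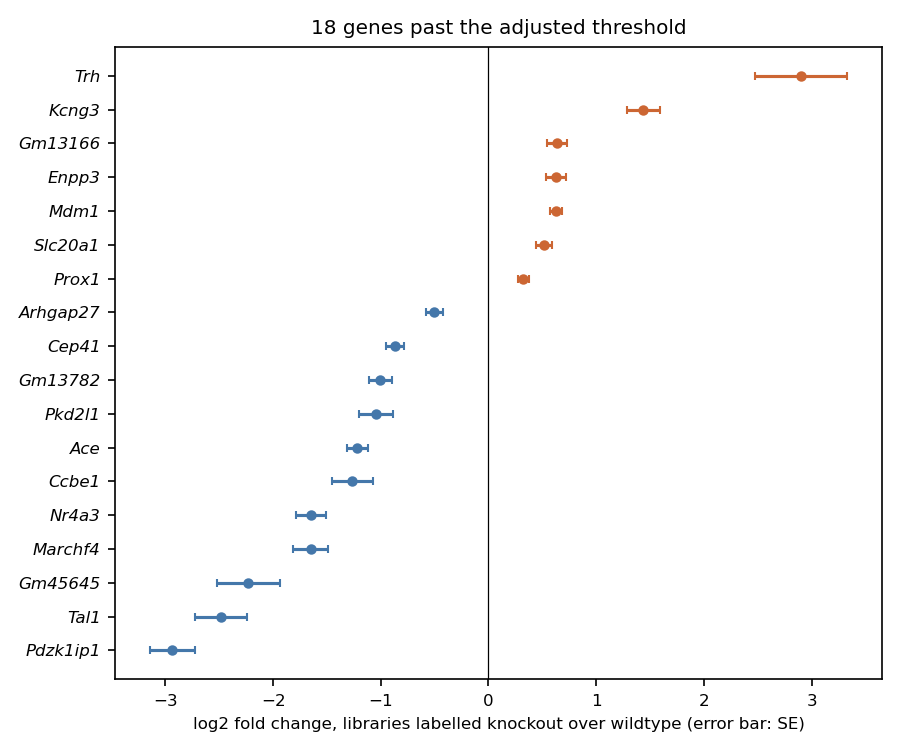
Log2 fold change of 18 genes past the adjusted threshold, libraries labelled knockout over wildtype (horizontal axis, log2 units; points are edgeR estimates from 4 libraries per group, error bars are SE). The estimates run from -2.94 for Pdzk1ip1 to 2.90 for Trh, and Prox1 lies at 0.33.

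Supporting cell genes were compared because Prox1 is expressed in pillar and Deiters cells. Of 11 tested genes of the Deiters cell list, 1 fell over all genes (Pdzk1ip1), and 3 were lower when adjusted over the list alone, namely Pdzk1ip1, the protease gene Prss23 (log2 fold change -0.39 ± 0.07) and the secretase gene Bace2 (-0.35 ± 0.10). The list as a whole was lower, with a median log2 fold change of -0.13 and an adjusted p of 3.64e-05 by limma's camera with Benjamini-Hochberg adjustment, and adjusted p = 0.33 with an estimated correlation. It was the single list of 32 that also passed with fry, limma's test of whether a set's genes move one way (Benjamini-Hochberg adjusted p = 0.0184). Of its genes 10 lay below 0 and 1 above, but Pdzk1ip1 at -2.94 lay far from the next lowest, Fgf3 at -0.50 ± 0.23. The list's mean was -0.44, and the list was not tested without Pdzk1ip1, so how far its calls rest on that gene is not known. In the pillar cell list, 0 of 12 genes passed over all genes and 1 passed adjusted over the list alone, the Notch effector gene Hey2 at 28.3 ± 2.30 CPM in the libraries labelled knockout against 21.1 ± 0.96 CPM in wildtype (SD, n = 4 per group; log2 fold change 0.42 ± 0.07). The growth factor receptor gene Fgfr3, on both lists, had a log2 fold change of -0.13 ± 0.05. Among 23 pan-supporting cell genes, 0 passed over all genes and Hey2 alone passed adjusted over the list alone, with Sox2 at 0.02 ± 0.06, Sox9 at -0.00 ± 0.08 and Jag1 at 0.01 ± 0.06. None of the 9 inner phalangeal and border cell genes passed either way, and the lowest p belonged to Hey1 (-0.14 ± 0.06).

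Genes of the Notch and FGF pathways, which pattern the organ of Corti, showed a few members with higher counts in the libraries labelled knockout. Of 22 Notch pathway genes, 0 passed over all genes and 2 were higher adjusted over the list alone, Hey2 and Rbpj, the DNA-binding partner of Notch (0.27 ± 0.06). Of the 22 genes, 10 lay above 0 and 12 below, among the latter Nrarp at -0.22 ± 0.07 and Hes5 at -0.10 ± 0.08, which did not pass either way. Of 19 FGF pathway genes, 0 passed over all genes and 1 was higher adjusted over the list alone, Fgf20, a ligand needed for formation of the outer compartment of the epithelium, at 2.16 ± 0.19 against 1.18 ± 0.15 CPM (SD, n = 4 per group; log2 fold change 0.87 ± 0.17). Hey2 and Fgf20 were higher in each of the 4 libraries labelled knockout than in each wildtype library. Neither list passed as a whole by camera with Benjamini-Hochberg adjustment (adjusted p = 0.547 for Notch and 0.626 for FGF), and in both the median lay below 0 (-0.04 and -0.00) while the mean lay above it (0.00 and 0.03), the test pointing down for Notch and up for FGF. None of the 19 BMP, 21 Wnt or 20 planar cell polarity genes passed over all genes or adjusted over the list alone. In these lists the lowest p belonged to Smad9 (0.30 ± 0.10), the Wnt antagonist gene Notum (-0.35 ± 0.09) and Vangl1 (-0.21 ± 0.08). The camera test with Benjamini-Hochberg adjustment gave adjusted p = 0.626, 0.0641 and 0.0850.

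Hair cell genes leaned lower by small amounts. None of 41 tested hair cell genes passed over all genes or adjusted over the list alone, 30 had a log2 fold change below 0, and the median was -0.08. Atoh1, which specifies hair cells, had 0.18 ± 0.11, Pou4f3 had 0.02 ± 0.07 and Myo7a had -0.12 ± 0.07. The list was lower by limma's camera with Benjamini-Hochberg adjustment (adjusted p = 0.0347), with adjusted p = 0.65 with an estimated correlation. It did not pass without wildtype library 4, without library 2 or 3 labelled knockout, without the wildtype libraries 1 and 3 together, with the lncRNA share as a covariate, with the stricter filter or with protein-coding genes alone. In the outer hair cell list, 2 of 12 genes were higher adjusted over the list alone and 0 over all genes: Neurod6 (1.12 ± 0.33, from 0.27 ± 0.07 CPM in wildtype) and the transcription factor gene Ikzf2 (0.23 ± 0.07). The motor protein gene Slc26a5 had -0.54 ± 0.25, and the list did not pass (adjusted p = 0.856 by camera with Benjamini-Hochberg adjustment), its median of -0.06 and the test pointing down and its mean of 0.02 up. None of the 9 inner hair cell genes passed either way, with Slc17a8, a glutamate transporter gene, at -0.27 ± 0.13 (list adjusted p = 0.0544 by camera with Benjamini-Hochberg adjustment). The list was called lower in 9 of 23 alternatives. No gene of the 29 on tip links and stereocilia passed (list adjusted p = 0.297 by camera with Benjamini-Hochberg adjustment). That list was called lower with the sex score and with the stria score as a covariate (adjusted p = 0.00513 and 0.0193 by camera with Benjamini-Hochberg adjustment).

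Lists on innervation did not pass as a whole in the test with genotype as the single factor, and those of spiral ganglion neurons and of glia did in some other fits. Of 46 axon guidance genes, 0 passed over all genes and 1 was lower adjusted over the list alone, the semaphorin gene Sema5a (log2 fold change -0.30 ± 0.07), lower in each of the 4 libraries labelled knockout than in each wildtype library. Nrp2, a semaphorin receptor gene, had -0.24 ± 0.08. None of 13 neurotrophin genes passed either way, with Bdnf at -0.00 ± 0.12 and Ntf3 at 0.11 ± 0.12. None of 21 spiral ganglion neuron genes passed, with Tubb3 at -0.12 ± 0.21, Nefl at -0.04 ± 0.15 and Scg2 at -1.17 ± 0.46. Scg2 had 8.69 CPM in wildtype library 1 and 2.33 to 4.10 CPM in the other wildtype libraries, and its log2 fold change ran from -1.74 to -0.02 over the alternatives. Of the Schwann and satellite glia list, 0 of 14 genes passed, and Pmp22, a myelin gene, had -0.15 ± 0.06. The adjusted p of these 4 lists by camera with Benjamini-Hochberg adjustment was 0.163, 0.547, 0.297 and 0.297. The spiral ganglion neuron list was called lower without wildtype library 3 (adjusted p = 0.000303 by camera with Benjamini-Hochberg adjustment), without library 1 labelled knockout (0.0427), without the wildtype libraries 1 and 3 (0.00230) and with the lncRNA share as a covariate (0.0220). The Schwann and satellite glia list was called lower with the sex score (adjusted p = 0.00413 by camera with Benjamini-Hochberg adjustment), with the stria score (0.000254) and without the wildtype libraries 1 and 3 (0.0147).

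Other epithelial and cellular lists passed by camera without any single member passing. The greater epithelial ridge, the medial epithelium beside the organ of Corti, had 15 of 16 genes below 0, with a median of -0.13, Calb1 at -0.16 ± 0.06 and Itih5 at -0.27 ± 0.10 (adjusted p = 0.00291 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.538 with an estimated correlation). Cell cycle genes had 25 of 29 below 0, with a median of -0.08, Mcm3 at -0.20 ± 0.08 and Mki67 at -0.08 ± 0.06 (adjusted p = 0.00139 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.336 with an estimated correlation). Cell adhesion and cytoskeleton genes had 19 of 23 below 0, with Cdh1 at -0.28 ± 0.09 and Nectin3 at 0.14 ± 0.05, and immediate early and stress genes 14 of 17, with Klf4 at -0.29 ± 0.10. Both of these lists had adjusted p = 0.0111 by camera with Benjamini-Hochberg adjustment, and adjusted p = 0.538 and 0.33 with an estimated correlation. The cell adhesion list did not pass without wildtype library 3 or without library 2 labelled knockout. It also did not pass with the stria score, the sex score or the lncRNA share as a covariate, or without the wildtype libraries 1 and 3 (adjusted p = 0.775, 0.0933, 0.363 and 0.303 by camera with Benjamini-Hochberg adjustment). The greater epithelial ridge list did not pass without the wildtype libraries 1 and 3 or with the lncRNA share (adjusted p = 0.0718 and 0.363 by camera with Benjamini-Hochberg adjustment). With the lncRNA share the cell cycle and the immediate early and stress lists did not pass either (0.0529 and 0.110). The cell adhesion and the immediate early and stress lists did not pass with protein-coding genes alone, nor the latter with the stricter filter. None of the 12 lateral epithelium genes passed either way (Nupr1 at -0.51 ± 0.17), nor any of the 12 apoptosis and p53 genes (Mdm2 at 0.11 ± 0.06), and both lists had adjusted p = 0.297 by camera with Benjamini-Hochberg adjustment.

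Among lists of tissues around the organ of Corti, those of stria vascularis and melanocytes, mesenchyme, cartilage and bone, vascular and lymphatic endothelium and erythroid cells were lower in the libraries labelled knockout with the preset correlation, and none of them with an estimated correlation. The vestibular, skeletal muscle and macrophage lists did not pass. In the stria vascularis and melanocyte list, 0 of 12 genes passed over all genes and 7 were lower adjusted over the list alone: the potassium channel subunit gene Kcne1 (-2.65 ± 0.51), Bsnd (-2.72 ± 0.76), Tyr (-2.02 ± 0.68), Esrrb (-1.91 ± 0.52), Dct (-1.64 ± 0.40), Pmel (-0.96 ± 0.22) and Kcnq1 (-0.52 ± 0.18). The list's median was -0.74 and its adjusted p 3.64e-05 by camera with Benjamini-Hochberg adjustment, with adjusted p = 0.376 with an estimated correlation. Kcne1 had 13.9, 4.54, 8.52 and 1.94 CPM in the wildtype libraries 1 to 4 and 0.85 to 1.90 CPM in the libraries labelled knockout. The mean log2 CPM of the list was 3.67 ± 0.65 in wildtype and 2.78 ± 0.19 in the libraries labelled knockout (SD, n = 4 per group; exact permutation p = 0.0571, two-sided). Without the wildtype libraries 1 and 3, a choice made after the data were seen, 2 genes were called higher and 7 lower over all genes, and the median of this list was -0.39.

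**Figure D3:**
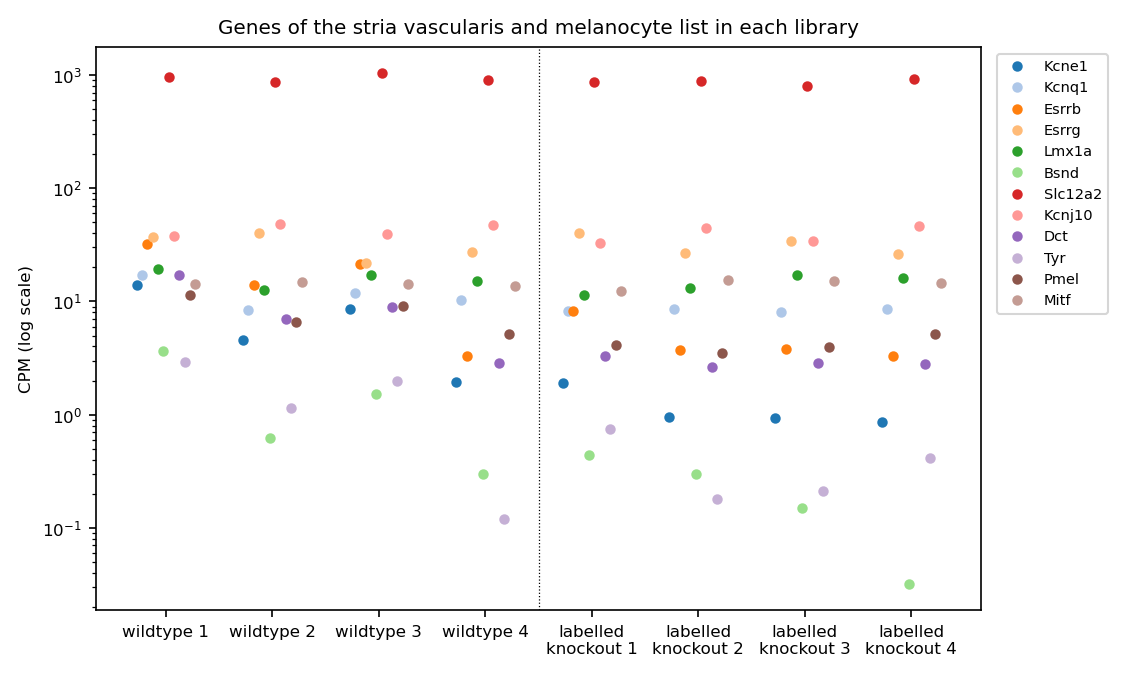
CPM values (vertical axis, log scale) of the 12 tested genes of the stria vascularis and melanocyte list in each of the 8 libraries, 1 colour per gene, with the dotted line parting wildtype from the libraries labelled knockout. Kcne1 ran from 1.94 to 13.9 CPM within wildtype, and wildtype library 4 lay close to the libraries labelled knockout for Kcne1, Esrrb and Dct.

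In the vestibular and roof epithelium list, 1 of 8 genes was lower adjusted over the list alone and 0 over all genes, the vestibular transcription factor gene Hmx3 (-1.34 ± 0.31), and the list did not pass (adjusted p = 0.0835 by camera with Benjamini-Hochberg adjustment). Hmx3 had 4.86, 3.04, 4.48 and 1.52 CPM in the wildtype libraries 1 to 4 and 1.10 to 1.53 CPM in the libraries labelled knockout. Over the alternatives its log2 fold change ran from -1.585 to -0.279. The mesenchyme list had 17 of 18 genes below 0 and a median of -0.12, with 0 genes passing over all genes and 2 lower adjusted over the list alone, Car3 (-0.53 ± 0.13) and the collagen gene Col1a1 (-0.45 ± 0.12), and adjusted p = 3.64e-05 by camera with Benjamini-Hochberg adjustment (adjusted p = 0.531 with an estimated correlation). No single gene passed in the cartilage and bone (11 genes, median -0.14), vascular endothelium (12 genes, median -0.15), lymphatic endothelium (6 genes, median -0.18) and erythroid lists (9 genes, median -0.30), where Ibsp had -0.49 ± 0.28, Flt1 -0.20 ± 0.07, Reln -0.39 ± 0.13 and Hba-a2 -0.54 ± 0.21. These 4 lists were lower by camera with Benjamini-Hochberg adjustment (adjusted p = 0.0304, 0.00267, 0.0454 and 0.0253), with adjusted p = 0.538, 0.531, 0.538 and 0.65 with an estimated correlation. Like the cell adhesion list, the mesenchyme list and these 4 lists did not pass with the stria score as a covariate (adjusted p from 0.561 to 0.932 by camera with Benjamini-Hochberg adjustment). None of the 5 passed without the wildtype libraries 1 and 3 either (0.110 to 0.834 by the same test). The score itself differed between the groups (means 3.67 in wildtype and 2.78 in the libraries labelled knockout), so these lost calls do not show that the lists vary with it. With the score the test pointed up for the vascular endothelium and erythroid lists. The cartilage and bone, lymphatic endothelium and erythroid lists each passed in 3 of the 8 fits with 1 library left out. The haemoglobin genes are near-identical copies whose reads may be split between them, so their separate levels are uncertain. None of the 5 skeletal muscle genes (Myh8 at -1.58 ± 0.52) or 14 macrophage genes (Aif1 at 0.69 ± 0.36) passed either way, and those lists had adjusted p = 0.297 and 0.591 by camera with Benjamini-Hochberg adjustment. The macrophage median was -0.02 and its mean 0.01, the test pointing down.

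Over all 32 lists, 12 were lower and 0 higher with the preset correlation, 0 passed in either direction with an estimated correlation, and 31 medians lay below 0. Random protein-coding lists matched on expression also had medians mostly below 0, from -0.0459 (greater epithelial ridge) to 0.0124 (skeletal muscle). The count of medians below 0 thus does not by itself show a lean. The FGF and the inner phalangeal and border cell lists, for example, lay at percentiles 87.1 and 88.1 of their random lists. Median log2 fold changes were -0.03 over 15272 protein-coding genes and 0.24 over 3550 lncRNA genes. The share of counts in lncRNA genes was 2.16 ± 0.41% in wildtype and 2.57 ± 0.40% in the libraries labelled knockout (SD, n = 4 per group; exact permutation p = 0.2, two-sided). With this share as a covariate, chosen after the data were seen, 4 lists were lower.

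**Figure D4:**
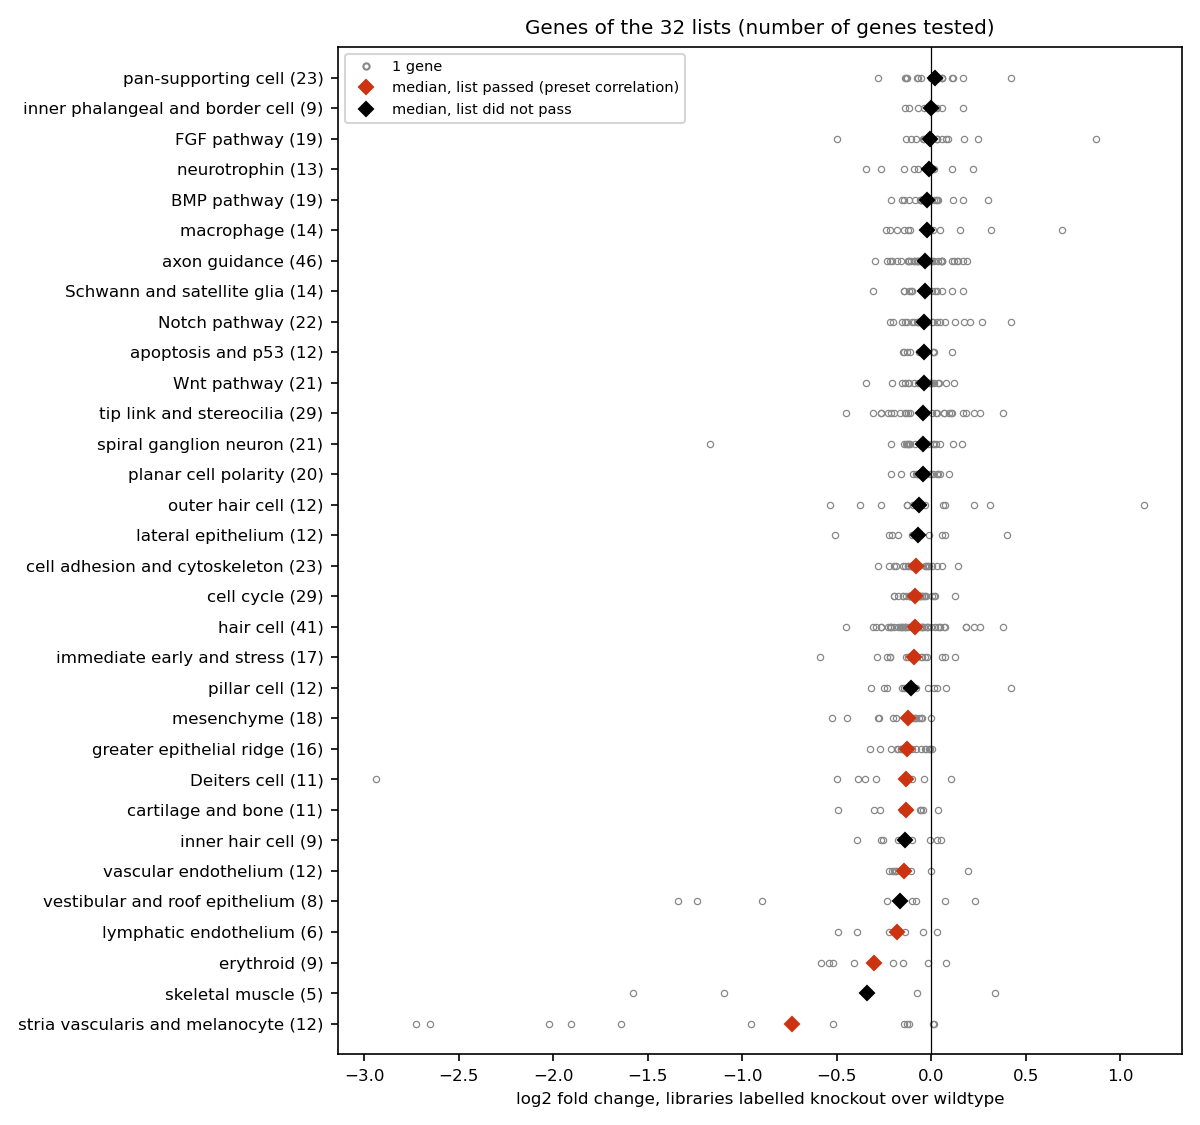
Log2 fold change, libraries labelled knockout over wildtype (horizontal axis), of each tested gene (open circles) in the 32 lists, with the number of tested genes in brackets. Diamonds are list medians, red for the 12 lists that passed by camera with the preset correlation and black for the others, and 31 of the 32 medians lie below 0.

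The authors' deposited table of the same comparison held 36 genes higher and 50 lower at an adjusted p under 0.05. All 19 genes called here were among those 86 in the authors' deposited table, and all 86 had the same sign in the edgeR fit. Across 20581 genes, which are not independent replicates, the log2 fold changes of the authors' deposited table and of the edgeR fit had a Pearson r of 0.99991 and a Spearman rho of 0.99992. Both rest on the same counts, as the rerun of DESeq2 showed, so the shared calls and signs are no independent support. Among the genes of the fixed lists, the authors' deposited table called Hey2, Rbpj and Fgf20 higher, with log2 fold changes of 0.42, 0.26 and 0.87, and Prss23, Pdzk1ip1, Sema5a, Col1a1, Car3, Kcne1, Pmel and Hmx3 lower. In the authors' deposited table Prox1 was also higher, with a log2 fold change of 0.32 and an adjusted p of 2.77e-05 from DESeq2.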

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

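The tests of Prox1 below, the test of the range of the stria score, and the use of an interval to judge the ratio of the stria medians were chosen after the results were seen. The other tests were chosen before the value they measure was seen, and the covariates and left-out libraries they use were added after the data were examined.

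Among 118 groups of 4 libraries examined (48 genes and 11 library measures in both genotypes), 5 held a library whose distance from the others exceeded Dixon's 95% limit. Chance flags about 1 in 20 groups, or 5.9 of these. Wildtype library 4 held 21.4 CPM of Trh, against 4.14 to 5.80 CPM in the other wildtype libraries. Library 4 labelled knockout held 68.4 CPM of Pmp22, against 60.6 to 61.5 CPM. Library 1 labelled knockout lay apart in total counts, at 29910000 against 32550000 to 32610000. The same library held 1.90 CPM of Kcne1 against 0.85 to 0.95 CPM, and a stria score of 3.07 log2 CPM against 2.67 to 2.70.

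Prox1 was higher in all 4 libraries labelled knockout. A swap of 1 library between the groups is argued against, since 0 libraries lay inside the range of the other group. A larger share of supporting cells is argued against by the other 43 pillar, Deiters and pan-supporting genes, whose median log2 fold change of -0.04 (-0.0379, 95% bootstrap interval -0.124 to 0.0168) lay below that of Prox1 by more than its SE of 0.0496. An exchange of all 8 labels would give the direction of the observed log2 fold change of 0.325, with Prox1 kept at 0.798 of the wildtype level. It cannot be told apart, since no size of the loss was predicted and the other genes of the design carry no known direction. Counting of reads outside the deleted part may explain a kept level with a lost protein and also cannot be told apart, since Prox1 is counted as 1 whole gene, and a biological increase of transcription of the deleted allele was not tested.

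The stria vascularis and melanocyte genes were lower in the libraries labelled knockout but ranged over 1.55 log2 CPM among the wildtype libraries in their mean, more than the 0.884 between the group means. The difference as measured was thus not of like size in every wildtype library, and Dct and Kcne1 ranged 6.05-fold and 7.18-fold within wildtype. The range cannot exclude a genotype difference of like size in every library, since variation between libraries on top of it would also widen the range. Without the wildtype libraries 1 and 3 the median log2 fold change moved from -0.74 to -0.39 (-0.386), a ratio of 0.524 with a 95% bootstrap interval over the 12 genes of 0.319 to 2.00. Those 2 libraries had the highest stria scores (4.37 and 3.91), so leaving them out lowers the wildtype mean of the list by construction, and the interval is over genes, not libraries. More lateral wall tissue in those 2 libraries may account for part of the difference and cannot be told apart from a smaller difference between genotypes. Of the 12 list genes, Slc12a2, the most abundant at 805 to 1054 CPM, and Kcnj10 are also expressed by other cochlear cells, and had log2 fold changes of -0.12 and -0.13. Lmx1a, Esrrg and Mitf of the same list had -0.14 ± 0.15, 0.01 ± 0.18 and 0.01 ± 0.09 (SE), so the fall was not shared by all its genes. A genotype difference in the lateral wall itself stays open and was not tested.

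The lists leaned lower, 12 of 32 passing with the preset correlation. For a trend of fold change with expression level, 16 lists lay at or under the 2.5th percentile of 10000 random protein-coding lists matched on expression. Genes were drawn there independently, so genes that vary together can also give such percentiles, and this count cannot decide. The random medians lay between -0.0459 and 0.0124, and those of the 12 lists between -0.737 (stria vascularis and melanocyte) and -0.0803 (cell adhesion and cytoskeleton). Such a trend by itself thus gave smaller falls than those of the 12 lists. A shift of protein-coding against other genes is argued against as the whole cause, since 7 lists were still lower with protein-coding genes alone. With the share of lncRNA counts as a covariate 4 lists were lower, 3 of them among the 12, so a difference in RNA composition between libraries may account for part of these calls, although a covariate also widens the error of each estimate. A biological difference of cell composition between the genotypes stays open as well.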

How the results depend on the processing

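The 4 alternatives named as added below were chosen after the results were seen, and all others before. For genes called over all genes other than Prox1, 393 alternative values were computed: all kept their direction, 309 passed the threshold and 84 did not. Of 634 values for named genes that were not called, 622 stayed so, 12 passed and 0 changed direction. Of 276 values of lists called lower, 193 passed, 82 did not and 1 reversed, the vascular endothelium list, with a median of 0.02 (0.0197) under the added stria score. There the test of the erythroid list also pointed up, with a median of -0.08. Of 459 values of lists not called, 34 were called lower and 1 higher. Where a result changed, the cause was not tested, except that fewer libraries or genes enter some of the fits.

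Against 7 genes higher, 12 were found with no filter, 35 with DESeq2, 2 with the sex score, 2 at an adjusted p under 0.01 and, with the added alternatives, 2 without the wildtype libraries 1 and 3, 1 with the stria score and 11 with the lncRNA share. Against 12 genes lower, 24 were found with no filter, 48 with DESeq2, 22 with quality weights in limma-voom, 7 with the sex score, 7 without the wildtype libraries 1 and 3 and 7 with the stria score. Leaving out 1 library gave 2 to 7 genes higher, with 2 without wildtype library 1 and without libraries 2 or 3 labelled knockout, and 3 without wildtype library 3 or library 1 labelled knockout. It gave 8 to 20 genes lower, the 20 without library 4 labelled knockout.

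The log2 fold change of Prox1 was 0.33 (0.327) with the sex score, 0.28 (0.280) without the wildtype libraries 1 and 3, 0.29 (0.294) with the stria score, and 0.30 (0.296) to 0.34 (0.342) when 1 library was left out. It no longer passed in the fits with the sex score, the stria score or those 2 libraries left out, with adjusted p from 0.315 to 0.997 in edgeR's test with Benjamini-Hochberg adjustment, and passed in 11 of 22 alternatives (adjusted p from 3.04e-05 with DESeq2 to 0.997). Leaving out any library but number 4 labelled knockout ended its call.

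Against 12 lists lower, 0 were found with an estimated correlation, 1 with fry, 6 without the wildtype libraries 1 and 3 (4 of the 12, with the spiral ganglion neuron and the Schwann and satellite glia lists), 4 with the lncRNA share (3 of the 12, with the spiral ganglion neuron list), 7 with protein-coding genes alone, and 7 to 15 when 1 library was left out, the 7 without library 2 labelled knockout. Of the lists called lower, the erythroid list was lost without wildtype library 1 or 4 or library 2, 3 or 4 labelled knockout. The cartilage and bone list was lost without wildtype library 1, 2 or 4 or library 2 or 3 labelled knockout, and the lymphatic list without wildtype library 1 or 3 or library 1, 2 or 3 labelled knockout. Of the others, the inner hair cell list was called without wildtype library 1 or 2 or library 4 labelled knockout, and the Wnt list without wildtype library 2 or 4 or library 4 labelled knockout. The pillar cell list was called without wildtype library 2 or library 4 labelled knockout, the vestibular and macrophage lists without wildtype library 4, and the lateral epithelium list without library 4 labelled knockout. The stricter filter ended the calls of the cartilage and bone, lymphatic, hair cell and immediate early lists, and protein-coding genes alone these and cell adhesion. The sex score ended those of the vascular endothelium, cartilage and bone, lymphatic and cell adhesion lists, no filter that of cartilage and bone, and removal of mitochondrial, haemoglobin and ribosomal RNA genes those of the erythroid and lymphatic lists. With the sex score the inner hair cell, pillar cell, lateral epithelium, tip link, Wnt and Schwann and satellite glia lists were called lower, and with the stria score the inner hair cell, tip link and glia lists. The inner hair cell list was also called with upper quartile scaling and both forms of limma-voom, the Wnt list with the latter 2, the pillar cell list with quality weights and the skeletal muscle list with no filter. Against 0 lists higher, 1 was found with the stria score, the macrophage list.

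No pairing of the samples by replicate number was seen: libraries with the same number had deviations from their group means that correlated at 0.112, 0.214, -0.275 and -0.137 across genes, and none correlated best with its own number. With so few libraries, a pairing hidden by other variation is not excluded. With the replicate number as a block, 3 genes were higher and the log2 fold change of Prox1 was 0.33 (0.325), not past the threshold. The block added calls of the inner hair cell and vestibular lists.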

Other observations

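Of the tests below, those of neighbours and of genes near Prox1 and Emx2 were chosen after the results were seen. The others were chosen before the value they measure was seen, with the lncRNA share and the stria score added as covariates after the data were examined.

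The deposited comparison reached further genes outside the fixed lists, named here after their values were seen. In the authors' deposited table the retinoic acid synthesis gene Aldh1a1 had a log2 fold change of -0.82 and Frzb, a secreted Wnt antagonist, one of -0.91, both called lower there. In the edgeR fit their adjusted p after Benjamini-Hochberg adjustment was 0.0738 and 0.0816. Emx2os, the antisense neighbour of Emx2, had a log2 fold change of 0.61 and an adjusted p of 0.00283 from DESeq2 in the authors' deposited table, and 0.62 with an adjusted p of 0.216 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Reads of Emx2os and Emx2 cannot be told apart where the counting strand is not given. Lars2, also named after its values were seen, had 298 CPM in library 3 labelled knockout and 17.4 to 27.9 CPM in the other 7 libraries.

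The 8 libraries can be split into 4 and 4 in 35 ways, and 2 of these, the real one included, called at least the 19 genes of the real split, so chance is not excluded at a share of 0.05. The highest other split called 2208 genes and set the wildtype libraries 1, 3 and 4 with library 4 labelled knockout against the rest, while 30 splits called 0. That count points to a structure of the samples other than genotype, and the former 4 libraries had at most 2.36% of counts in lncRNA genes while the latter had at least 2.51%. A difference in that share is argued against as the source of the 19 calls, since with it as a covariate their median absolute log2 fold change was 1.16, against 1.22 without, and 16 of the 19 passed. For the lists, 3 of the 35 splits called at least 12 (highest other 13), so chance is not excluded there either. The split of wildtype libraries 1 and 2 with libraries 1 and 3 labelled knockout against the rest, which mixes the genotypes evenly, called 9 lists.

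The 12 genes called lower kept a median log2 fold change of -1.29 with the stria score as a covariate, against -1.33 without, so a larger amount of lateral wall tissue in some wildtype libraries is argued against as their whole cause, although 7 of the 12 passed in that fit. For those that did not, the SE rose, from 0.294 to 0.420 for Gm45645 at log2 fold changes of -2.23 and -2.22, and for Pkd2l1 and Ccbe1 the log2 fold change also moved, from -1.05 to -0.72 and from -1.26 to -0.89. The test does not cover the genes called higher, of which Trh moved from 2.90 to 1.97.

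Among the 18 called genes placed in the RefSeq order of GRCm38, 2 pairs were neighbours, Tal1 with Pdzk1ip1 and Cep41 with Gm13782. Of 10000 random sets of as many genes, 0 held 2 such pairs and 171 held at least 1 (permutation p = 1e-04, the smallest they can give). The second pair overlaps and may share reads, so it may be 1 signal, and the p for 2 pairs then overstates the case against neighbours by chance. For Tal1 with Pdzk1ip1 alone, the 171 draws with at least 1 pair are the measure, in a test chosen after the pairs were seen. Tal1 and Pdzk1ip1 may share regulation or a linked sequence variant, neither of which was tested. Of the 100 tested genes nearest to Prox1, 12 had an unadjusted p under 0.05, against 7.25% of other genes (one-sided Fisher's exact p = 0.0591), which leaves linked variants around the floxed locus open. Near Emx2 it was 7 of 100 against 7.28% (one-sided Fisher's exact p = 0.598), a share that does not exclude linked variants that change only a few genes there.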
